A study of Homo sapiens with 4 samples.

How the data were processed

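The data were 4 ChIP-seq libraries from K562, a human cell line derived from chronic myeloid leukaemia in blast crisis. H3K27ac, acetylation of lysine 27 on histone H3 and a mark of active promoters and enhancers, was profiled in 1 library from cells given 1 uM daunorubicin for 18 h and in 1 library from untreated cells. Each condition also had 1 input library, sequenced without an antibody. Daunorubicin is an anthracycline, a drug that intercalates into DNA and poisons topoisomerase II. Groups were taken from the antibody and treatment labels.

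Per the submitters' processing notes, the tools named were Bowtie2 2.3.4.3, deepTools 3.2.1 and MACS2 2.1.1, and the genome builds hg19 and hg38 were both named. The parameters of these tools, the peak threshold, the use of the inputs in peak calling and any removal of duplicate reads are not given in the sources used here. The authors deposited 1 peak list per library, without column headings, so peaks of the 2 H3K27ac libraries were called separately. The only measured value in each list is a score per peak, deposited by the authors as the caller wrote it, and its formula is not given in the sources used here. The score was used to rank, describe or filter peaks within a list, with the exception of the stricter score and of the tests in the closing section that set it beside that of the other list, whose scores may differ in scale. Read counts and coverage were not used here, so the depth of each library is unknown, and the number of called peaks can move with depth and with enrichment.

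The lists carried sequence names of hg38. Of 20037 protein-coding genes, 62.5% (95% Wilson interval 61.9 to 63.2) had a daunorubicin peak within 1 kb of an annotated end and 58.4% (57.7 to 59.1) an untreated one, against 19.2% and 13.9% after the peaks had been shifted by 100 kb. Gene positions came from a RefSeq gene table of GRCh38.p14, the same build. Coordinates are on hg38 and counted from 1. That table gave the start and end of each gene but no strand and no transcripts. The design fixed before the data were examined had placed promoters at 5' ends. Both ends of a gene were used in its place: a peak at a gene end lay within 1 kb of either annotated end of any of 59679 genes of all biotypes, a gene-body peak overlapped a gene elsewhere, and the rest were intergenic. A gene end can therefore be a promoter or a 3' end, and exons, introns and UTRs were not told apart.

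Peaks of the libraries were counted as shared if they overlapped by at least 1 bp. Peaks of both H3K27ac lists were classed by overlap, and regions were formed by merging overlapping peaks. The marked length of a gene was the number of base pairs covered by peaks within 50 kb of either end, with the windows of a gene merged, and each gene's difference is daunorubicin minus untreated. Windows of neighbouring genes overlap, so 1 peak can count for several genes. Marked length does not require a peak at the gene's own ends. Overlap expected by position alone came from 100 shuffles within chromosomes. Shares carry 95% Wilson intervals, which cover counting error only. With 1 library per condition there was no test between conditions and no p-value. The 25 gene lists (404 genes, 403 matched by symbol and 1 by synonym) were fixed before the data were examined. The median difference of each list is given as its percentile among 10000 random lists of the same size, matched on the mean marked length of both libraries. These percentiles describe the 2 libraries and do not measure variation between cultures.

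Named genes followed a rule fixed before the data were examined, and those printed were picked among its genes after their values were seen. They were the ALDH family members with a peak within 50 kb, with the 6 ALDH1 genes always included, and up to 4 members of each other list with the largest absolute difference. To these were added the 10 genes with the largest gain and the 10 with the largest loss, skipping neighbours within 100 kb, and the gene nearest (within 100 kb) to the 10 highest-scoring regions of each unshared class. Genes named outside this rule are marked as chosen after their values were seen, and some genes that the rule named are not reported here.

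The 11 alternatives chosen before the data were examined were a stricter score of at least 43 in both lists (the untreated median), equal numbers of the 38626 highest-scoring peaks, removal of peaks on input peaks, chromosomes 1 to 22 and X only, a reciprocal overlap of 50%, a gap of 1 kb for unshared peaks, gene ends within 2.5 kb, windows of 10 kb and 100 kb, list means, and random lists matched on the untreated library. The 2 alternatives chosen after seeing the data were ends of protein-coding genes only and windows over the gene span extended by 50 kb. Overlap functions were tested on simulated peak sets of 60000 and 40000 peaks against bedtools and gave the same counts. The list percentile was tested on 60 simulated lists of 20 genes, drawn from 20000 simulated genes: 5 unshifted lists fell outside the central 95%, and 60 shifted lists lay above it. The planted shift was larger than the simulated noise of a single gene, so the simulation does not show that smaller shifts would be found. It also left the matching value unchanged. Matching on the mean of both libraries, as used here, can take up part of a gain, and this was not simulated. Simulated genes varied independently, so the simulation did not cover lists that hold neighbouring genes with the same peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.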

Results

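The series concerned ALDH1 expression, enhancers gained with anthracyclines and drug resistance in acute myeloid leukaemia. Each of the 4 libraries stood for 1 condition and 1 target, so there were no replicates and no difference below has a replicate check. The daunorubicin H3K27ac library had 65118 peaks covering 57.0 Mb, with a mean width of 875 bp. The untreated library had 38626 peaks covering 36.0 Mb, with a mean width of 931 bp. The ratios of daunorubicin to untreated were 1.69 for peaks, 1.59 for covered length and 0.94 for mean width. Scores, which are the authors' own values, had a median of 41 (quartiles 24 and 83) in the daunorubicin list and 43 (24 and 120) in the untreated list. The input libraries had 87 peaks with daunorubicin and 92 without it. Only 36 daunorubicin and 33 untreated H3K27ac peaks overlapped an input peak, 0.0553% (0.0399 to 0.0765) and 0.0854% (0.0608 to 0.12).

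The first comparison asked whether H3K27ac peaks at the ALDH1 genes differed between daunorubicin-treated and untreated cells. At ALDH1A1, which encodes a cytosolic retinaldehyde dehydrogenase, the daunorubicin library had 8 peaks within the gene span and 50 kb on either side, and the untreated library had 4. The marked length there was 6630 bp with daunorubicin and 2619 bp without it, a ratio of 2.53. That difference of 4011 bp was 346 bp under the stricter score, 1579 bp with equal numbers of top-scoring peaks, 1116 bp in windows of 10 kb and 6860 bp in windows of 100 kb. At ALDH1A2, the retinaldehyde dehydrogenase best known from embryonic development, there were 9 and 5 peaks. ALDH1L1 and ALDH1L2, the cytosolic and mitochondrial 10-formyltetrahydrofolate dehydrogenases, had 3 against 1 and 5 against 4. ALDH1B1, a mitochondrial enzyme, had 4 against 2, and ALDH1A3 had 2 against 1. No peak at these 6 genes was called only in the untreated library, and no input library had a peak at any of them. Of all protein-coding genes, 73.2% had a region called only with daunorubicin within 50 kb of an end. For regions called only without it the share was 29.0%.

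ALDH1A1 lies on chromosome 9 from 72900671 to 72953053. All 4 of its untreated peaks were also found with daunorubicin. One of the 4 peaks called only with daunorubicin crossed the higher end of ALDH1A1 (72952854 to 72953754, score 20), beside a shared peak inside the gene at 72951851 to 72952569. The untreated peak there, at 72952209 to 72952712, lay within 1 kb of it, so this end was marked in both libraries. With a gap of 1 kb that peak would not count as unshared. The widest of the 4 lay 35569 bp below the lower end (72862890 to 72865102, 2213 bp, score 41). The other 2 lay above the higher end, at 72982381 to 72982657 (score 14) and 72983699 to 72984233 (score 12). None of the 4 scores exceeded the median of the daunorubicin list, 41.

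**Figure D1:**
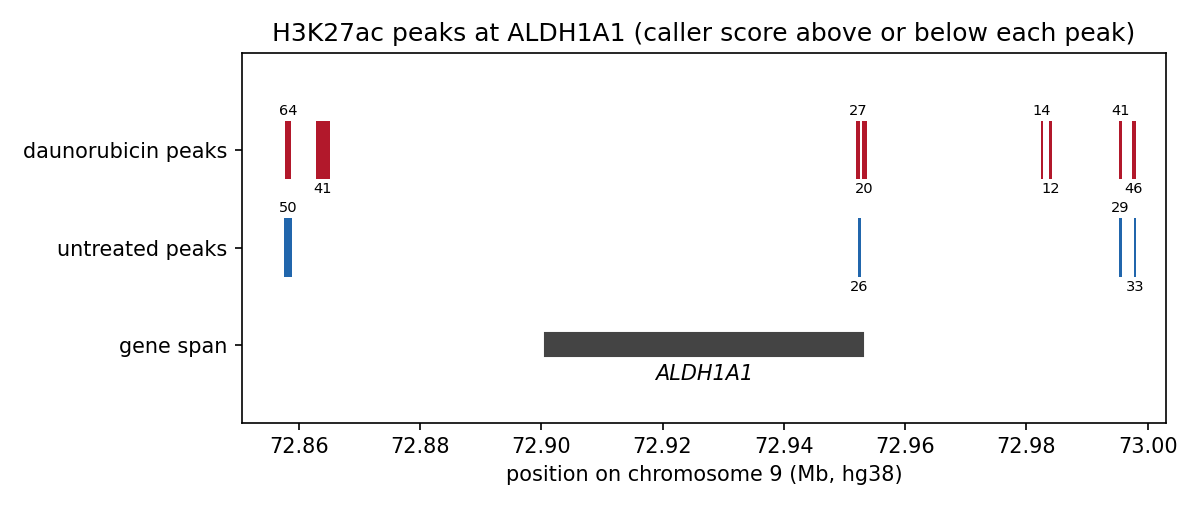
Peaks of both H3K27ac libraries at ALDH1A1, drawn to scale along chromosome 9 (Mb, hg38), with the gene span and 50 kb on either side. Coloured blocks are peaks, the number at each is its caller score, and the daunorubicin row holds 8 peaks against 4 in the untreated row.

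At ALDH1A2 (chromosome 15, 57953429 to 58065711) the peak called only with daunorubicin that had the highest score, 103, lay 44893 bp above the higher end, at 58110604 to 58111026. An untreated peak at 58111763 to 58112277 lay within 1 kb of it, so with a gap of 1 kb it would not count as unshared. Peaks within 50 kb of the ends of ALDH1A2 covered 6179 bp with daunorubicin and 3164 bp without it. ALDH1L1 (chromosome 3, 126103570 to 126197945) had an end marked only with daunorubicin, by 2 peaks of score 17 and 22, and its marked length was 2559 bp against 1318 bp. ALDH1L2 had 5275 bp against 3590 bp, and the order was turned in windows of 10 kb. ALDH1B1 had 3069 bp against 2170 bp, but 19 bp less with daunorubicin under the stricter score. ALDH1A3 had 1646 bp against 1715 bp, and no peak at its ends in either library. With equal numbers of top-scoring peaks, 4 regions at the 6 ALDH1 genes were called only with daunorubicin and 2 only without it.

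Across the ALDH family, many but not all of whose members oxidise aldehydes to acids, the marked length was longer with daunorubicin at 13 of 19 genes, shorter at 5 and equal at 1. With equal numbers of top-scoring peaks the split was 10 longer and 8 shorter. Of all protein-coding genes with a difference, 87.2% were longer in the full lists and 64.8% with equal numbers of peaks. ALDH7A1 had 8762 bp against 5310 bp, ALDH6A1 6278 bp against 4229 bp, and ALDH3A2, the fatty aldehyde dehydrogenase, 1747 bp against none. ALDH3B2 (4360 bp against 2910 bp) and ALDH3B1 (6951 bp against 6008 bp) were also longer. ALDH4A1 (3773 bp against 2707 bp), ALDH9A1 (5478 bp against 4553 bp) and ALDH18A1 (4589 bp against 3756 bp) were longer in the full lists and shorter with equal numbers of peaks. Shorter with daunorubicin were ALDH16A1 (13908 bp against 14916 bp), ALDH8A1 (1559 bp against 2154 bp), ALDH5A1 (832 bp against 1289 bp) and ALDH2 (8692 bp against 8985 bp), of which ALDH8A1 and ALDH2 turned under other settings. ALDH7A1, ALDH3B2 and ALDH8A1 had no peak at their ends in either library. The family's median difference, 943 bp, stood at percentile 39.6 of matched random lists, whose median was 1034 bp, and at 86.1 with equal numbers of peaks, with 18.0 to 86.1 as the range over all settings. The list stayed inside the central 95% in each.

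The second comparison asked how the whole sets of H3K27ac regions differed. Merging both lists gave 33264 regions in both libraries, 30150 called only with daunorubicin and 4140 called only without it, a ratio of 7.28. Of the untreated peaks, 89.3% (89.0 to 89.6) were overlapped by a daunorubicin peak, against 4.15% after shuffling. Of the daunorubicin peaks, 53.7% (53.3 to 54.1) were overlapped by an untreated peak, against 2.51% after shuffling. With equal numbers of top-scoring peaks, which makes the unshared counts nearly equal by construction, 9582 and 9532 regions were called in 1 library only. The ratio was 8.38 under the stricter score and 2.97 with a reciprocal overlap of 50%.

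Regions called only with daunorubicin lay mostly away from gene ends. Of these, 12.4% (12.02 to 12.77) were at a gene end, 60.6% in a gene body and the rest intergenic, whereas 42.1% (41.6 to 42.6) of the shared daunorubicin peaks were at a gene end. The gene-body share of regions called only without daunorubicin was 64.8%. No shares for randomly placed peaks were computed. Regions called only without daunorubicin had 13.6% (12.5 to 14.6) at a gene end, but under the stricter score the shares were 15.6% with and 32.99% without daunorubicin, against 63.2% of shared peaks. Peaks called only with daunorubicin were narrow and of low score, with a median width of 435 bp and a median score of 26 against 1097 bp and 74 at shared peaks. The share of daunorubicin peaks with no untreated peak ran from 85.9% (85.1 to 86.8) in the lowest of 10 score bins to 0.415% (0.285 to 0.603) in the highest. For untreated peaks it ran from 35.3% (33.8 to 36.8) to 0.0259% (0.00457 to 0.147).

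**Figure D2:**
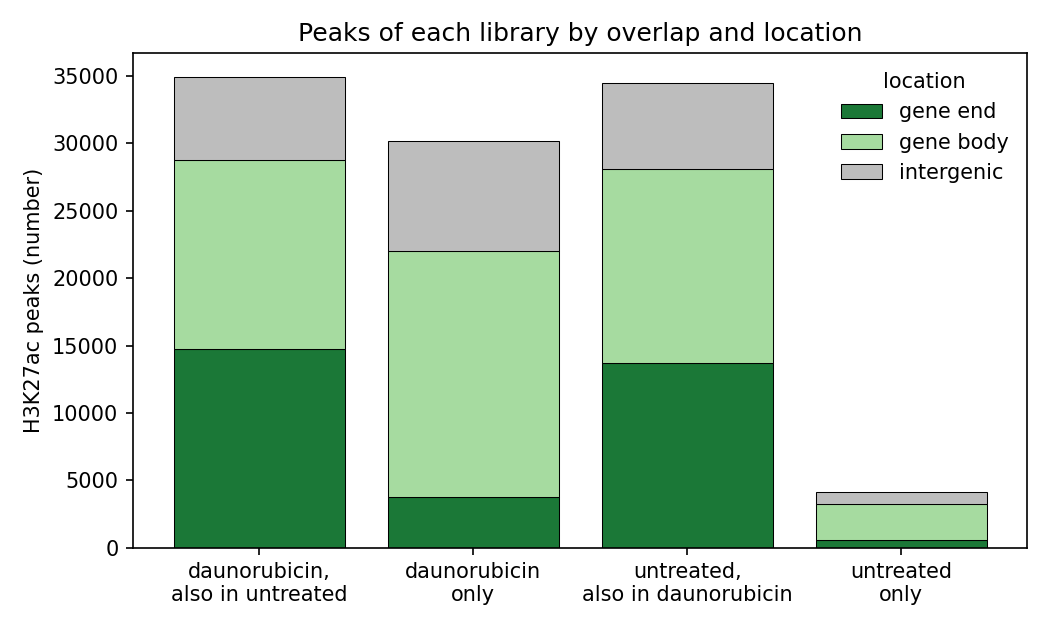
Number of H3K27ac peaks in each library by whether the other library had an overlapping peak, with bars divided by location. The 30150 peaks called only with daunorubicin lay mainly in gene bodies, as did those called only without it, and 12.4% lay at gene ends. No shares for randomly placed peaks were computed.

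**Figure D3:**
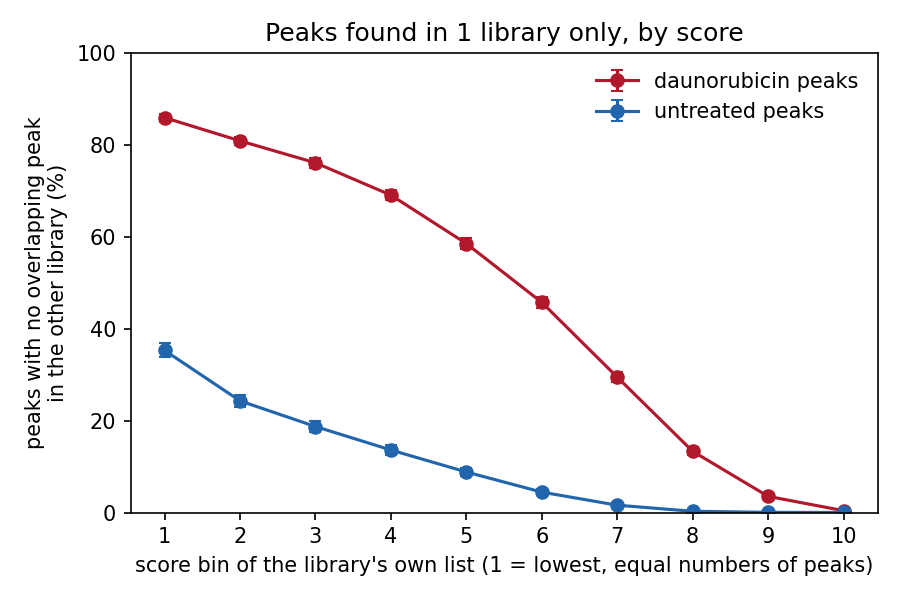
Percent of peaks with no overlapping peak in the other library, by 10 equal score bins of each library's own list. Bars are 95% Wilson intervals, and the share falls from 85.9% to 0.415% for daunorubicin peaks and from 35.3% to 0.0259% for untreated peaks.

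Among the 10 highest-scoring regions called only with daunorubicin, the first was intergenic on chromosome 2 (238777592 to 238778148, score 318), 69937 bp from TWIST2, a bHLH transcription factor gene. Others lay in the body of TBC1D22B (chromosome 6, 37302391 to 37304063, score 258), 75365 bp from TMPO, a nuclear lamina gene (score 257), and 67820 bp from BMAL1, a core circadian clock gene (score 251). Regions at an end of HERC6 (score 206) and PTPRF, a receptor tyrosine phosphatase gene (score 200), were also called only with daunorubicin. Among the 10 highest-scoring regions called only without daunorubicin was a region inside DGCR8, a microRNA processing factor gene, 4737 bp from its nearest end (chromosome 22, 20084978 to 20085544, score 246). Regions at an end of DHODH, a pyrimidine synthesis gene (score 177), and ZFPM1, which encodes the GATA1 cofactor FOG1 (score 156), were also called only without it. DHODH nevertheless had a daunorubicin peak within 1 kb of an end, and its marked length was longer with daunorubicin (5231 bp against 2855 bp). At ZFPM1 the marked length was 10953 bp against 10849 bp.

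At gene level, an end was marked in both libraries at 11548 protein-coding genes, only with daunorubicin at 983, only without it at 150 and in neither at 7356. With equal numbers of top-scoring peaks that order was turned, with 393 genes marked only with daunorubicin and 510 only without it. Marked length was longer with daunorubicin at 15289 genes and shorter at 2250, with a median difference of 1249 bp over the 17543 genes marked in either library. With equal numbers of peaks it was longer at 11041 genes and shorter at 5994, 64.8% against 87.2% longer in the full lists, and the median difference was 374 bp.

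The gene with the largest gain was RHEX, a regulator of erythropoietin signalling (chromosome 1, 206053173 to 206102449), with 17737 bp marked with daunorubicin and 2282 bp without it. Next were ELL2, an RNA polymerase II elongation factor gene (20042 bp against 6255 bp), TNRC6B, a microRNA silencing gene (21035 bp against 7427 bp), and YPEL2 (19314 bp against 6090 bp). The rest of the 10 were CRADD, an adaptor of caspase signalling (24428 bp against 11402 bp), GAB2, a docking protein of kinase signalling (25975 bp against 12951 bp), TENT5C (18129 bp against 5414 bp), ME3 (17623 bp against 4921 bp), DIPK1A (29708 bp against 17437 bp) and TMEM164 (19324 bp against 7156 bp). Each of the 10 had at least 9 regions within 50 kb that were called only with daunorubicin.

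Losses were smaller. RNF224 had 11425 bp with daunorubicin and 16340 bp without it, MATK, a kinase that acts on SRC family kinases, 3743 bp against 7047 bp, and UTF1, a chromatin factor of pluripotent cells, 2453 bp against 5521 bp. RBM38, an RNA-binding protein gene, had 5313 bp against 8375 bp, KIFC2 13319 bp against 16346 bp, CCDC57 12305 bp against 15201 bp and R3HDM4 13180 bp against 16012 bp. PWWP2B (3837 bp against 6662 bp), KLHL30 (2505 bp against 5279 bp) and BORCS8-MEF2B (7290 bp against 10063 bp) completed the 10. RNF224, MATK and UTF1 had no peak at their ends in either library.

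The third comparison asked whether genes of pathways linked to anthracyclines or to blood cells stood apart from random genes with like marking. Of the 25 lists, 1 lay outside the central 95% of random lists, against 1.25 by chance. It was the interferon response, with a median difference of 200 bp against 739 bp for random lists (percentile 1.25), and it moved inside the central 95% under 5 alternatives (range 0.96 to 56.8). Ranges given after a percentile are over the full lists and the 9 alternatives that recompute it, and 16 of the 25 lists had percentiles on both sides of the random median among these settings, so most lists had no stable side. In the interferon list 13 of 17 genes were longer and 2 shorter, or 9 and 6 with equal numbers of peaks. Neighbouring members shared peaks, with OAS1, OAS2 and OAS3 each at 809 bp against 736 bp. MX1 and MX2 each had 389 bp against none (these 5 genes were chosen after their values were seen). Random lists were not matched for such neighbours, so the percentile counts some loci more than once. IFI6 had 7392 bp against 4112 bp and IRF9 11560 bp against 12728 bp, the last with its order turned in windows of 10 kb.

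Genes that p53 activates had longer marking with daunorubicin at 19 of 20 members (16 with equal numbers of peaks), with a median difference of 2486 bp against 1640 bp for random lists (percentile 94.1). The list lay above the central 95% under 3 alternatives, at 98.8 each, and stood at 95.4 with equal numbers of peaks, 83.8 with list means and 75.8 in windows of 10 kb, where 13 genes were longer and 6 shorter. TNFRSF10B, a death receptor gene, had 11118 bp against 6045 bp, GADD45A, a growth arrest gene, 16436 bp against 11626 bp, BTG2, an antiproliferative gene, 14640 bp against 9883 bp, and ZMAT3 9030 bp against 4712 bp. All 18 AP-1 and immediate early genes had longer marking (percentile 79.9, at lowest 70.1), 14 of them with equal numbers of peaks. The list stood at 97.1 under the stricter score and exactly at the upper bound of the central 95% with equal numbers of peaks. ATF3, a stress-responsive transcription factor gene, had 8879 bp against 3715 bp, KLF6 14453 bp against 9472 bp, and DUSP1, a MAP kinase phosphatase gene, 11891 bp against 7095 bp. ATF3 had no peak at its ends in either library. BCL2 family and apoptosis genes stood at percentile 66.8 (range 55.3 to 96.0), with 17 longer and 2 shorter, or 15 and 4 with equal numbers of peaks, and with the proapoptotic PMAIP1 at 13864 bp against 7496 bp, XIAP at 11700 bp against 5551 bp and BCL2 at 8417 bp against 3496 bp. DNA damage response genes stood at 40.2 (range 11.3 to 83.0), with 18 longer and 3 shorter, or 14 and 7 with equal numbers of peaks, and XRCC5 at 11136 bp against 5363 bp.

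All 24 NRF2 targets and regulators, the antioxidant programme, had longer marking with daunorubicin, and 15 did with equal numbers of peaks. Their median of 1318 bp stood at percentile 21.96 against a random median of 1639 bp, and at 84.6 in windows of 10 kb (range 16.4 to 84.6). GCLC, which encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, had 9033 bp against 3599 bp. TXNRD1, a thioredoxin reductase gene, had 5735 bp against 1855 bp, NFE2L2, which encodes NRF2 itself, 9574 bp against 6091 bp, and ME1 6736 bp against 3509 bp. Other antioxidant enzymes stood at percentile 62.5 (range 1.28 to 81.5), with 19 longer and 3 shorter, or 11 and 10 with equal numbers of peaks. Among them were GLRX at 12648 bp against 6374 bp and SESN3 at 6104 bp against 1627 bp. The retinoid pathway, which ALDH1 enzymes feed, stood at 90.5 (range 61.0 to 93.9), with 13 of 18 genes longer, 11 with equal numbers of peaks. DHRS9, a retinol dehydrogenase gene, had 15078 bp against 4650 bp and 14 regions called only with daunorubicin, RDH10 13016 bp against 7971 bp, and RARA, a retinoic acid receptor gene, 11749 bp against 7226 bp.

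Drug efflux and uptake genes stood at percentile 28.2 (range 21.7 to 89.1), with 7 of 11 longer and 2 shorter, or 5 and 4 with equal numbers of peaks. SLC22A16, a carnitine transporter that takes up anthracyclines, had 4421 bp against 281 bp, ABCC1, the exporter MRP1, 7666 bp against 4403 bp, ABCC5 9719 bp against 6647 bp, and ABCA2 4929 bp against 7293 bp, the last with its order turned in windows of 10 kb. Neither library had a peak within 1 kb of an end of SLC22A16. ABCB1, the exporter P-glycoprotein, chosen after its value was seen, had no peak within 50 kb of its ends in either library. Anthracycline metabolism stood at percentile 7.22 (range 2.18 to 24.5), with 9 longer and 2 shorter, or 4 and 6 with equal numbers of peaks. It held CBR3, a carbonyl reductase gene, at 5880 bp against 3758 bp, POR at 7407 bp against 5340 bp and NDUFS7 at 8229 bp against 9694 bp. All 7 topoisomerase and topoisomerase repair genes had longer marking (percentile 74.9, range 39.8 to 84.0), 6 of them with equal numbers of peaks, among them TOP1 (17808 bp against 9111 bp) and TOP2A and TOP2B, which encode the daunorubicin targets (9806 bp against 6392 bp and 4744 bp against 2712 bp).

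Of blood cell lists, all 25 erythroid genes had longer marking with daunorubicin (percentile 27.4), 14 of them with equal numbers of peaks. The list stood at 96.5 under the stricter score and at 96.6 in windows of 10 kb (range 15.7 to 96.6). TAL1 had 10506 bp against 6261 bp, EPB42 6357 bp against 2677 bp, and SLC4A1, the band 3 anion exchanger, 13336 bp against 9679 bp. EPB42 had no peak at its ends in either library. Megakaryocyte genes stood at percentile 65.2 (range 21.99 to 74.7), with 13 longer and 1 shorter, or 9 and 5 with equal numbers of peaks. They included ITGB3 at 14614 bp against 10184 bp and the platelet chemokine genes PPBP at 2673 bp against 87 bp and PF4 at 2353 bp against none. PPBP and PF4 lie close together, so their windows largely overlap and their gains are not separate. Neither gene had a peak at its ends in either library. Monocyte and granulocyte genes stood at 41.7, and at 99.2 under the stricter score, outside the central 95%. Of these, 11 were longer and 4 shorter, or 10 and 5 with equal numbers of peaks, and the members with the largest differences included CEBPE at 13805 bp against 6120 bp, CSF1R at 9748 bp against 2867 bp and S100A8 at 6569 bp against 2045 bp. CEBPE, CSF1R and S100A8 had no peak at their ends in either library. Stem and progenitor genes stood at 93.6 (range 69.1 to 96.3), with 10 longer and 1 shorter, or 8 and 3 with equal numbers of peaks. They included MEIS1 at 7692 bp against 3240 bp, HOXA9 at 5133 bp against 2063 bp and MYB at 14704 bp against 10242 bp, the last shorter with daunorubicin with equal numbers of peaks.

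**Figure D4:**
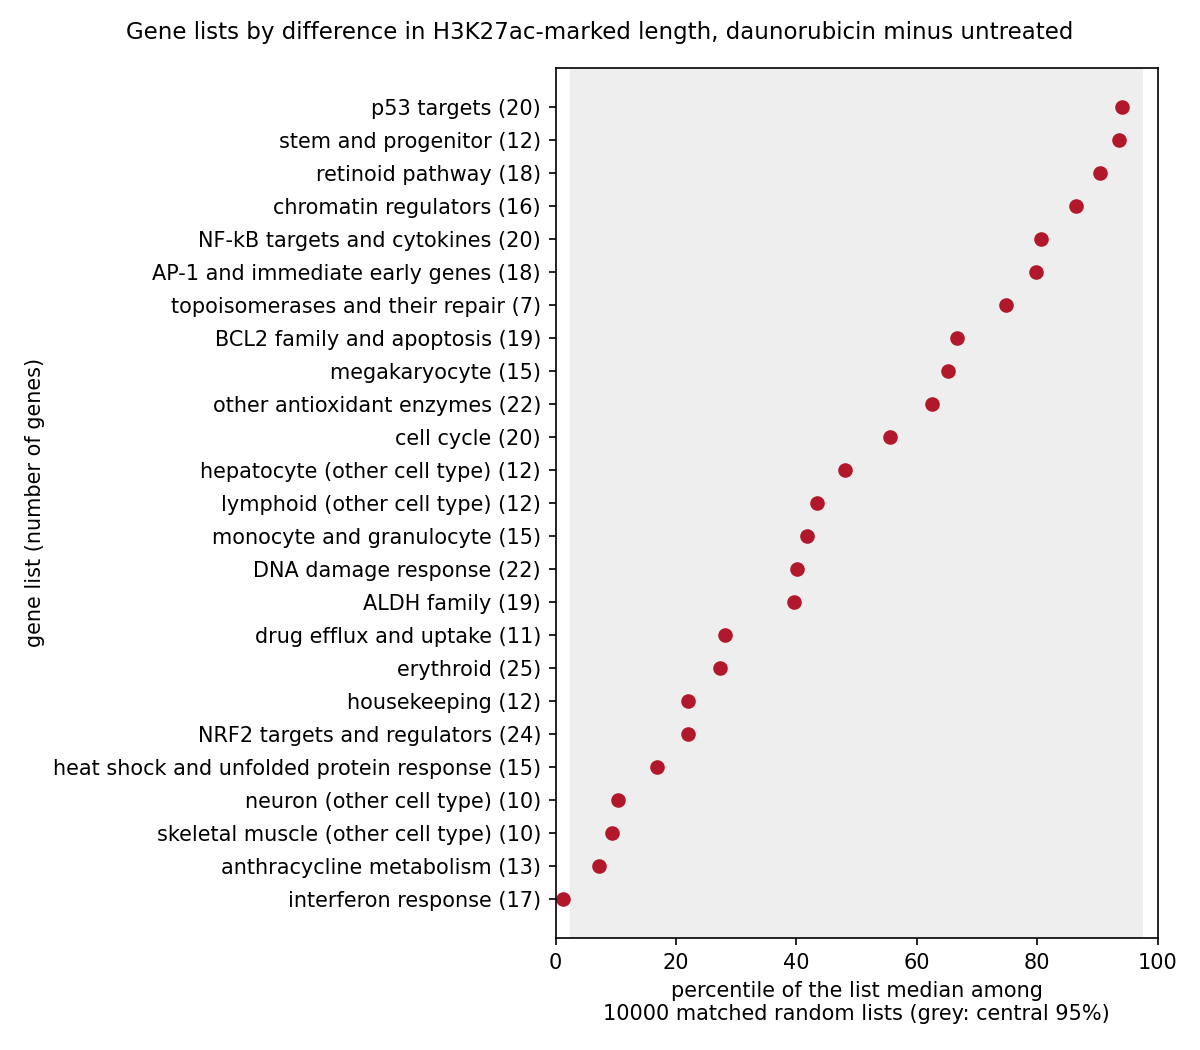
Percentile of each gene list's median difference in marked length among 10000 matched random lists, 1 point per list, with the number of genes in parentheses. The grey band is the central 95%, and only the interferon response, at percentile 1.25, lies outside it.

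The remaining lists lay inside the central 95% in the full lists. Chromatin regulators stood at percentile 86.4 (EZH2 11405 bp against 5824 bp, KMT2A 13708 bp against 8097 bp), but at 18.3 under the stricter score and 7.77 in windows of 10 kb (range 7.77 to 96.7). Of these, 14 were longer and 2 shorter, or 12 and 4 with equal numbers of peaks. NF-kB targets and cytokines stood at 80.7, range 55.5 to 87.7 (CXCL8 9471 bp against 4054 bp, CXCL1 8131 bp against 3828 bp), and cell cycle genes at 55.5, range 21.8 to 81.3 (AURKB 17705 bp against 14231 bp, CDK1 5823 bp against 2553 bp). NF-kB genes were longer at 19 of 20, or 14 with 5 shorter at equal numbers of peaks, and cell cycle genes at 20 of 20, or 16 with 4 shorter. Heat shock and unfolded protein response genes stood at 16.9, range 4.42 to 43.2 (HSP90AB1 13327 bp against 8285 bp, XBP1 7663 bp against 4022 bp) and housekeeping genes at 21.98, range 11.6 to 40.3 (YWHAZ 12118 bp against 8927 bp). The heat shock list had 13 longer and 2 shorter, but 7 and 8 with equal numbers of peaks, where its median was -43 bp, and the housekeeping list had 11 and 1, or 7 and 5. Markers of cell types other than K562 stood at percentile 48.1 for hepatocytes (CYP3A4 10318 bp against 6116 bp), 43.4 for lymphoid cells (CD3E 10140 bp against 4031 bp), 10.3 for neurons (GRIN1 10397 bp against 12861 bp, turned in windows of 10 kb) and 9.34 for skeletal muscle (DES 6857 bp against 8338 bp, turned in windows of 100 kb). Their ranges were 19.8 to 98.4, 40.5 to 96.9, 0.35 to 61.6 and 0.77 to 65.2. CYP3A4 had no peak at its ends in either library. Marking was longer with daunorubicin at 9 of 12 hepatocyte, 9 of 12 lymphoid, 5 of 10 neuron and 4 of 10 skeletal muscle genes. Among equal numbers of top-scoring peaks it was longer at 6, 8, 1 and 2 of them and shorter at 4, 2, 6 and 3.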

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

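Depth is unknown and each group had 1 library, so no call rests on a test between conditions. No paired analysis was possible because each group has 1 library and no result comes from a test. The planned use of 5' ends of any transcript was not run. The alternatives with ends of protein-coding genes and with the gene span extended by 50 kb were chosen after seeing the data. For the values below that moved between settings the cause was not tested, except where the construction of an alternative sets the value. Removing peaks on input peaks, or keeping chromosomes 1 to 22 and X, moved none of the summaries, lists or genes by the criteria used. Of 665 gene values, 399 stayed within 1/3 of the main value, 251 moved farther without a change of sign and 15 reversed. In the 4 alternatives with another score, number of peaks or window only 119 of 380 stayed, and of 225 list values, 15 crossed a bound of the central 95%.

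With equal numbers of top-scoring peaks, 38626 per list by construction, 75.3% of untreated and 75.2% of daunorubicin peaks were overlapped. Regions called only with and only without daunorubicin numbered 9582 and 9532, near equal by construction, and 14.1% and 15.2% of them were at gene ends against 46.7% of shared daunorubicin peaks. Gene ends marked in 1 library only numbered 393 with and 510 without daunorubicin, the median gene difference was 374 bp, and the ALDH1 genes had 4 regions only with and 2 only without daunorubicin. The interferon list moved to percentile 34.4 and the neuron list to 0.35. ALDH4A1 (-358 bp), ALDH9A1 (-897 bp), ALDH18A1 (-752 bp) and MYB (-1596 bp) reversed.

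With the stricter score, 31496 daunorubicin and 19374 untreated peaks were left, with 58.8% and 92.0% overlapped. Regions in 1 library only numbered 12980 and 1549, with 15.6% and 32.99% at gene ends against 63.2% of shared daunorubicin peaks. Gene ends in 1 library only numbered 648 and 297, the median difference was 799 bp, and the ALDH1 genes had 6 regions only with daunorubicin. Above the central 95% were 2 lists, p53 targets (98.8) and monocyte and granulocyte genes (99.2), and below it were 0, with the interferon list at 5.43. ALDH1B1 (-19 bp), ALDH4A1 (-358 bp), ALDH8A1 (1345 bp) and ALDH9A1 (-574 bp) reversed.

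With a reciprocal overlap of 50%, 65.1% of untreated and 38.6% of daunorubicin peaks were shared and 13463 peaks were only in the untreated list. Gene-end shares were 16.4% for daunorubicin only, 47.3% for shared and 18.1% for untreated only. With a gap of 1 kb, shared peaks were 92.3% and 58.8%, and gene-end shares 11.3% for daunorubicin only and 40.2% for shared. Gene-end shares for daunorubicin only, shared and untreated only were 22.1%, 48.7% and 23.99% within 2.5 kb, and 5.81%, 33.4% and 7.29% with ends of protein-coding genes.

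In windows of 10 kb the median difference was 358 bp, 6 regions at the ALDH1 genes were only with daunorubicin, 0 lists lay below the central 95% and the interferon list stood at 56.8. ALDH1L2 (-521 bp), ABCA2 (212 bp), IRF9 (482 bp) and GRIN1 (5 bp) reversed. In windows of 100 kb the median was 2255 bp, 1 ALDH1 region was only in the untreated library, and 2 lists lay above the central 95%, p53 targets (98.8) and hepatocyte markers (98.4). Other antioxidant enzymes stood at 1.28 and the interferon list at 2.8, and ALDH2 (1293 bp), ALDH8A1 (491 bp) and DES (2125 bp) reversed. Over the extended gene span the median was 1312 bp. With list means, 4 lists lay below the central 95%, the interferon list and anthracycline metabolism (2.18), neurons (1.15) and skeletal muscle (0.77). With random lists matched on the untreated library, 1 list lay above the central 95%, p53 targets (98.8), and 0 below it, with the interferon list at 3.47.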

Other observations

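The tests of the low-scoring peaks, of the order of scores and of gene density were chosen after the results had been seen.

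Shorter marking with daunorubicin was more frequent near chromosome ends. Of the 10 genes with the largest loss of marked length, 8 lay within 5 Mb of an end of the chromosome, RNF224, MATK, UTF1, KIFC2, CCDC57, R3HDM4, PWWP2B and KLHL30, and of the 10 with the largest gain, 0 did. The distance of 5 Mb was chosen after these genes had been seen, and an end was taken as position 1 or the last gene or peak of the chromosome. Among all marked protein-coding genes within 5 Mb of a chromosome end, 780 of 2354 (33.1%, 31.3 to 35.1) had shorter marking with daunorubicin, against 1470 of 15189 farther away (9.68%, 9.22 to 10.2). Most genes with a loss thus lay farther away, and the median difference was a gain in both places, 403 bp near the ends and 1419 bp elsewhere. Genes near and far were not matched on untreated marked length, and the intervals count neighbouring genes that share peaks as separate. The share of daunorubicin peaks with no untreated peak was lowest on chromosome 19 (30.6%, 28.9 to 32.4), followed by 16 (39.9%) and 22 (40.0%), and highest on 15 (50.8%, 48.6 to 52.9).

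The first pattern weighed was the excess of regions called only with daunorubicin, 30150 against 4140: 79.6% of the daunorubicin-only peaks scored below the median of their list, but so did 93.9% of the untreated-only peaks in theirs. Higher depth or enrichment in the treated library could bring weak peaks over the calling limit, and weak regions gained with daunorubicin would give the same value, so the 2 cannot be told apart. For peaks of score 150 or more the test fixed beforehand went against that explanation: at 6876 shared peaks the 1st percentile of the untreated score was 35, above the lower quartile of 24. That bound was badly chosen, because the 34 daunorubicin-only peaks are only 0.492% of 6910 and lie beyond a 1st percentile, and 30 shared peaks of that size had an untreated score of 24 or less, so these strong peaks stay open. Of 25 untreated-only peaks of score 80 or more, 44.0% (26.7 to 62.9) had a daunorubicin peak within 1 kb, which leaves open whether a shift of peak borders or a lost peak is the reason, and an effect of daunorubicin itself stays open throughout because depth was not known.

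The second pattern was the lower standing of gene ends with daunorubicin: unshared minus shared peaks differed in gene-end share by -29.7 percentage points in the daunorubicin list, but also by -26.3 points in the untreated list. Most of this went with score. If score were the whole cause, peaks of like score were predicted to have like shares. Within 10 score bins -8.71 points (-9.56 to -7.87) were left with daunorubicin against -0.84 (-2.02 to 0.34) in the untreated list, a comparison chosen after the result. That prediction thus failed with daunorubicin, but the test cannot decide. A score measures strength with noise, so at like score the peaks also called in the other library can be the stronger ones. The untreated list is no like control, because 89.3% of its peaks were shared against 53.7% of daunorubicin peaks. A single change of scale between the libraries would keep the order of scores, yet among 30495 peaks paired one to one the median change of place of 12283 gene-end peaks against 18212 others was -4.99 percentage points (-5.42 to -4.60). Order is kept only without noise, however. Gene-end peaks had the higher scores (median 153 against 32 in gene bodies among shared untreated peaks). Noisier scores in the treated library could therefore also lower their place, which was not tested. Shorter marking was also more frequent among genes in the densest of 5 density bins than in the sparsest, 23.9% (22.5 to 25.3) against 8.32% (7.45 to 9.28), a difference of 15.5 percentage points. The bins were not matched on untreated marked length, whose median was 7514 bp in the densest and 2387 bp in the sparsest, so the densest genes had more to lose. These intervals also count neighbouring genes that share peaks as separate. Fewer GC-rich fragments in the treated library could give the differences at gene ends and in dense regions. They cannot be told apart from an effect of daunorubicin on promoters, because GC content was not used here and gene density goes with both.

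The third pattern was the longer marking at ALDH1A1, a member of the ALDH1 genes that the series title names. Among the 500 protein-coding genes of nearest untreated marked length (2498 to 2740 bp), 89.2% had longer marking with daunorubicin, with a median difference of 1396 bp. The difference of 4011 bp at ALDH1A1 stood at percentile 90.8 of them, inside the central 95%. Under the stricter score the difference was 346 bp, below the median of 799 bp over marked genes. With equal numbers of peaks it was 1579 bp, above the median of 374 bp. In the full lists the gain at ALDH1A1 thus lay within the spread of the increase in called length at genes of like marking. A specific effect of daunorubicin at ALDH1A1 was neither shown nor excluded by these peak lists.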
